A study of Bos taurus with 6 samples.

How the data were processed

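RNA was sequenced from primary mammary epithelial cells of Holstein cattle, either wild type or after disruption of the gene for the transcription factor KLF6 with CRISPR/Cas9. The labels give 3 libraries per genotype, 6 in all. Per the labels' protocols, RNA was extracted with TRIzol, treated with DNase I, and turned into libraries with the Ion Total RNA-Seq Kit v2. The labels do not say whether the 3 libraries of a genotype came from separate cultures or separately edited clones. All p-values therefore measure only the spread between these libraries, which may be technical.

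The authors deposited a table of raw counts per gene for the 6 libraries and a table of their own comparison. Per the submitters' processing notes, HISAT2 2.0.5 and featureCounts 1.5.0-p3 were used, and no roles or settings are given there. The genome build and annotation version, and the strand setting of the counting, are not given in the sources used here. The deposited counts are whole numbers, and they cover 28200 rows, of which 9473 had 0 counts in all libraries. Row names are Ensembl gene identifiers, apart from 630 rows of unnamed extra loci that held 0.807% to 0.884% of the counts of a library. Symbols, chromosomes, coordinates and biotypes were taken from the count table itself, which pairs 20327 of the rows with a symbol. A reference gene table of assembly ARS-UCD2.0 was at hand, but none of its entries carried an Ensembl identifier, so it was not used. Where a symbol stood on more than 1 row, the row with the most counts was used for the gene lists.

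The authors' deposited table lists 9532 genes, all at an adjusted p-value up to 0.0499, with a log2 fold change of knockout over wild type. The sample columns of the authors' deposited table hold a normalized signal, namely the counts divided by 1 factor per library, with a largest relative deviation over genes of 5.11e-15. To 6 digits, those factors were the size factors that DESeq2 gave here. The test behind the deposited p-value column is not given in the sources used here. No genes outside the authors' threshold are in that table, so their fold changes were compared only within it.

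Total counts ranged from 1.75e+07 to 1.87e+07 per library, and 15875 to 16322 genes had at least 1 count. The 10 most abundant genes held 7.49% to 8.70% of the counts. Intervals and floors given for rare transcripts cover counting error only, since the labels mention no molecular identifiers. Because strand use is not stated, reads from overlapping genes cannot be told apart with certainty. Of the 176 genes chosen by the naming rule, 27 overlap another expressed gene in the file's coordinates, among them FAS with ACTA2, TM7SF2 with VPS51, TJP3 with APBA3, COX4I1 with EMC8, HYOU1 with VPS11, MYH11 with NDE1, and IFIT1 and IFIT3 with LIPA. Genes with near-identical copies, such as ribosomal proteins with their pseudogenes, the IFIT and OAS1 families and the keratins, may share reads in the authors' counting, and their values are less certain.

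Knockout and wild-type libraries were compared with edgeR 4.0.16 (R 4.3.3, limma 3.58.1), using TMM scaling, the filterByExpr function with a minimum count of 10 and a minimum total of 15, robust dispersion estimates, the quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. The filter left 13390 genes. Levels are CPM (counts per 1e+06 counts of the TMM-scaled library), as mean ± SD over 3 libraries, and log2 fold changes are knockout over wild type ± SE. The SE was worked back from the test, as the size of the log2 fold change over the square root of the quasi-likelihood F. It therefore adds nothing to the p-value as a measure of precision. For a gene at 0 in all libraries of a genotype, the fold is a lower bound computed against 3 counts over the group. For a gene with 1 to 3 counts over a group, the ratio of counts is given with its 95% counting interval, since the fitted value then depends on edgeR's prior count.

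Chosen before the data were examined were 30 gene lists, 22 of pathways and 8 of cell type markers. Each list was tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 30 lists, and with fry. Camera was also run with a correlation estimated for each list. The pathway lists included fatty acid synthesis, triglyceride synthesis, fatty acid uptake, fatty acid oxidation, cholesterol synthesis, milk proteins, mTOR signalling, the G1/S and G2/M phases, TGF-beta, extracellular matrix, cell junctions, interferon, NF-kB, the unfolded protein response, hypoxia and glycolysis, oxidative phosphorylation, Kruppel-like factors, apoptosis, immediate-early and heat-shock genes, and ribosomal proteins. The marker lists covered luminal, basal, fibroblast, adipocyte, endothelial, leukocyte, pericyte and squamous cells.

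The naming rule was also set before the data were examined. It took KLF6, the 12 genes per direction with the largest fitted change, and up to 3 members per direction of each list by size of log2 fold change. The 12 genes had to be protein-coding with a symbol, past the threshold, at a mean of at least 5 CPM in the higher genotype, and without overlap of the genotypes. Other list members named below were chosen after their values were seen, because they are abundant or well known.

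The procedure was tested on counts simulated for this comparison, with the means of the 13390 tested genes and the library sizes of the data. Dispersions were those of the trend with abundance, not of each gene, so the simulated genes may be better behaved than the real ones. In it 200 single genes were changed, besides the 20 cholesterol synthesis genes, which were changed 2-fold as a list. Of 50 genes changed 1.2-fold, 36.0% were called in the right direction. The share was 78.0% at 1.5-fold, 96.0% at 2-fold and 96.0% at 4-fold. Of the other 13170 genes, 8 were called, and of 30 lists the only call was the list that had been changed. Genes were drawn independently of each other, so the simulation does not test list calls where genes move together. It also changed few genes, whereas 74.6% of the tested genes were called in the data.

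Alternatives set before the data were examined were other scalings (median of ratios, upper quartile, library size only, or without the 50 most abundant genes), DESeq2 1.42.0 and limma-voom, other filters, protein-coding genes only, a block for the replicate number, leaving out each library in turn, and stricter thresholds. An alternative that takes the median log2 fold change of each chromosome out of the knockout libraries was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.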

Results

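The study measured gene expression in bovine mammary epithelial cells, the cells that line the milk-producing gland, with and without a disrupted KLF6 gene. KLF6 is a zinc-finger transcription factor of the Kruppel-like family. There were 3 KLF6 knockout and 3 wild-type libraries, with total counts between 1.75e+07 and 1.87e+07. The comparison asks which transcripts differ in level when KLF6 is disrupted.

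KLF6 (ENSBTAG00000015188, chromosome 13, 44597240 to 44605699) fell 2.32-fold, from 519 ± 34.0 CPM in wild-type libraries to 224 ± 6.48 CPM in knockout libraries (n = 3 each). Its log2 fold change was -1.21 ± 0.05 (SE), with an edgeR adjusted p = 2.25e-13, and the 3 knockout libraries (224, 230 and 217 CPM) all lay below the 3 wild-type libraries (503, 496 and 558 CPM). Between 3897 and 4233 reads of KLF6 remained in a knockout library. The counts per gene do not show which part of the transcript was read, and an edit that shifts the reading frame need not lower the RNA. The authors' deposited table gives a log2 fold change of -1.20 for KLF6.

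**Figure D1:**
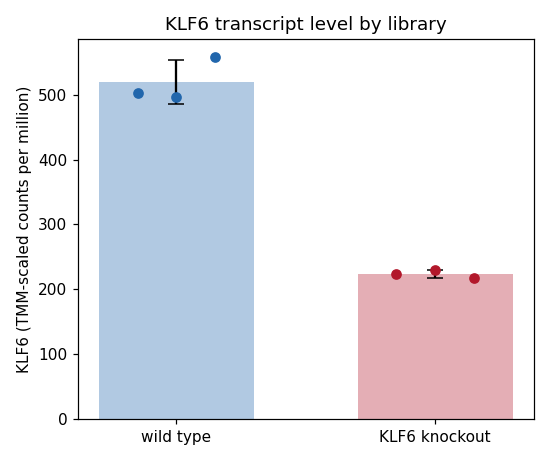
KLF6 level in CPM, TMM-scaled (vertical axis) in wild-type and knockout libraries. Points are libraries, bars are means and error bars are SD (n = 3 each). The knockout mean was 224 and the wild-type mean 519.

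Libraries with a disrupted KLF6 gene had more RNA of the cell cycle genes E2F1 and CCNB1, and less RNA of the lipid synthesis genes FASN and HMGCS1, the keratin gene KRT8 and the interferon-induced gene MX1. MMP14, a membrane-bound matrix metalloproteinase, stood at 588 ± 27.6 CPM in knockout libraries and was almost unread in wild type. SPARC, a matrix-binding glycoprotein, rose from 153 ± 8.71 to 2721 ± 28.5 CPM. SCD, which desaturates stearic acid, fell from 1598 ± 16.7 to 465 ± 8.12 CPM. KRT15, a basal keratin, fell from 953 ± 0.824 to 1.99 ± 0.751 CPM.

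By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 4963 genes rose and 5028 fell among 13390 tested, which is 74.6% of them. Many of these changes were small, with 4430 calls (44.3%) under 1.5-fold. At least 2-fold changes were found for 1449 genes that rose and 1538 that fell, at least 4-fold for 604 and 453, and at least 8-fold for 373 and 217. The first principal component of the expression values parted the genotypes and held 92.5% of the variance. The spread within a genotype was small, with a common biological coefficient of variation of 0.0558. Wild-type replicate 3 stood farther from its group, at 8.94 and 9.12 times the variance of pure counting against wild-type replicates 1 and 2, while the other pairs within a genotype lay between 2.26 and 2.94.

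Several genes were read in 1 genotype only. Among the 12 genes with the largest rise, MMP14 (chromosome 10, 21967557 to 21978162, build not given in the sources used here) had 31601 reads in the knockout libraries and 2 in wild type, a ratio of 16073 (counting interval 4449 to 132722). DDC, which makes dopamine and serotonin from their precursors, was at 33.7 ± 0.479 CPM in knockout libraries and 0 in wild type, at least 614-fold higher. The deubiquitinase gene USP26 was at least 938-fold higher, the palmitoyltransferase gene ZDHHC14 at least 518-fold, the engulfment receptor gene MEGF10 at least 223-fold, APBA2 at least 196-fold, MARK1 at least 176-fold and DOK5 at least 160-fold. SERPINA11 was at least 142-fold higher, the muscle and neuronal transcription factor gene MEF2C at least 137-fold and the metalloreductase gene STEAP1 at least 118-fold. AMN had 1935 reads against 1, a ratio of 1968 (counting interval 353 to 77784).

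In the other direction, FGFBP1, a carrier of fibroblast growth factors, was at 81.3 ± 3.68 CPM in wild type and 0 in knockout libraries, at least 1455-fold lower. The serine protease gene TMPRSS4 was at least 939-fold lower, RAB15 at least 264-fold, SLC35D2 at least 250-fold, AGMO at least 127-fold, and SPTLC3, a subunit of the first enzyme of sphingolipid synthesis, at least 123-fold. RBM44 and DRAXIN were each at least 115-fold lower. KRT15 had a log2 fold change of -8.90 ± 0.10. The kinase gene LYN had 603 reads in wild type against 1 in the knockout libraries (ratio 593, counting interval 106 to 23452), WNT3A 521 against 1 (ratio 512, interval 91.5 to 20268) and MICAL1 875 against 2 (ratio 430, interval 119 to 3557).

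Most tested genes of fatty acid and cholesterol synthesis fell. Of 13 tested members of the fatty acid synthesis and desaturation list, 11 fell and 2 rose. FASN, the fatty acid synthase, fell from 743 ± 53.6 to 299 ± 6.85 CPM, and SREBF1, a transcription factor that drives lipid synthesis genes, fell from 392 ± 0.992 to 118 ± 3.74 CPM. ELOVL6 fell by 2.11 ± 0.07 and FADS1 by 5.48 ± 0.30 on the log2 scale (-6.31 to -5.02 with a library left out), while ACACB and ELOVL5 rose (0.72 and 0.29). THRSP had 123 reads against 2 (ratio 60.5, counting interval 16.4 to 505). The list was lower by camera (adjusted p = 1.83e-06), with an adjusted p = 0.0912 with an estimated correlation. Of 20 cholesterol synthesis genes, 17 fell and 1 (TM7SF2, 0.38) rose, with camera adjusted p = 1.83e-06 and adjusted p = 0.0747 with an estimated correlation. HMGCS1 (-1.67 ± 0.06), SQLE (-1.64 ± 0.07), LSS (-1.48 ± 0.07) and SREBF2 (-1.34 ± 0.06) were among those that fell, whereas MVD did not pass the test (-0.05 ± 0.05).

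Fatty acid uptake and activation had 9 members that fell and 2 that rose among 12 tested (camera adjusted p = 0.0363, and adjusted p = 0.159 with an estimated correlation). FABP3, a fatty acid carrier, fell by 2.55 and ACSL6 by 2.14 on the log2 scale, while ACSL4 rose (1.03). Of 21 fatty acid oxidation genes and PPAR targets, 14 fell and 3 rose (camera adjusted p = 0.0474, and adjusted p = 0.206 with an estimated correlation). ACADVL, which starts the oxidation of very long chains, fell from 461 ± 16.8 to 149 ± 6.52 CPM, and ANGPTL4 rose (1.26). The adjusted p of both lists crossed the threshold under several alternatives, for example at 0.0501 and 0.0525 without wild-type replicate 1, and the uptake list also reached 0.0558 without wild-type replicate 3 and the oxidation list 0.0531 without knockout replicate 3. Triglyceride synthesis and lipid droplet genes went both ways, with 8 that rose and 7 that fell among 18 (camera adjusted p = 0.573, and adjusted p = 0.617 with an estimated correlation). In that list the lipid droplet coat gene PLIN2 rose (1.47 ± 0.10) and LPIN1 and DGAT1 fell (-1.53 ± 0.10 and -1.40 ± 0.07). Its median was 0.01, its mean was -0.19, and camera gave the direction as lower.

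The caseins, alpha-lactalbumin, the prolactin receptor gene PRLR and ELF5 had too few counts to be tested. Of the 7 tested members of the milk protein and prolactin list, 3 rose (SOCS2, STAT5B and JAK2) and 3 fell (CISH, B4GALT1 and STAT5A), with camera adjusted p = 0.857 and adjusted p = 0.869 with an estimated correlation. CISH, a feedback inhibitor of cytokine signalling, fell by 1.02 ± 0.11 on the log2 scale. STAT5A had a log2 fold change of -0.22 ± 0.08, which did not pass the test without wild-type replicate 3 (-0.15, edgeR adjusted p = 0.0973), without knockout replicate 1 (-0.19, adjusted p = 0.0789), without knockout replicate 3 (-0.20, adjusted p = 0.0746) or by DESeq2 (-0.21, adjusted p = 0.0724). The median of this list was 0.07 and its mean -0.02, with the camera direction lower.

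Most tested cell cycle genes rose. Of 35 G1/S and DNA replication genes, 32 rose and 0 fell (camera adjusted p = 1.37e-08, and adjusted p = 0.0854 with an estimated correlation). Of 37 G2/M and mitosis genes, 36 rose and 0 fell (camera adjusted p = 1.74e-10, and adjusted p = 0.159 with an estimated correlation). The transcription factor gene E2F1 rose from 21.5 ± 1.77 to 69.4 ± 3.16 CPM, and the cyclin genes CCNE1 and CCNB1 rose by 1.60 ± 0.10 and 1.55 ± 0.05 on the log2 scale. UBE2C, an enzyme of the anaphase-promoting pathway, rose from 87.8 ± 8.69 to 297 ± 2.96 CPM, and MKI67, a proliferation marker, from 122 ± 12.7 to 216 ± 14.9 CPM. The median change of both lists was below 2-fold, at 0.79 and 0.77.

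Apoptosis regulators had 11 that rose and 10 that fell among 29 (camera adjusted p = 0.317, and adjusted p = 0.415 with an estimated correlation). The pro-apoptotic gene BMF fell from 68.8 ± 3.17 to 2.29 ± 0.351 CPM, MCL1 fell (-1.17 ± 0.04), and BCL2 rose (1.18 ± 0.17).

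Of 32 matrix and remodelling genes, 21 rose and 8 fell (camera adjusted p = 2.04e-09, and adjusted p = 0.0747 with an estimated correlation). Besides MMP14 and SPARC, the collagenase gene MMP1 rose (3.12 ± 0.07), as did the urokinase receptor gene PLAUR (2.67 ± 0.06) and COL12A1 (2.69 ± 0.06). COL1A2 was at 5.18 ± 0.549 CPM in knockout libraries and 0 in wild type, at least 94.3-fold higher. COL7A1, named after the anchoring fibril collagen, fell from 135 ± 23.5 to 7.13 ± 0.997 CPM (the count file marks this locus as a pseudogene, and 3 loci of the same strand overlap it), and FBN1 and COL3A1 fell too (-2.61 and -1.52). Of 23 TGF-beta pathway genes, 11 rose and 7 fell (camera adjusted p = 0.0208, and adjusted p = 0.149 with an estimated correlation). The latent TGF-beta binding gene LTBP1 rose from 62.3 ± 3.98 to 1262 ± 5.48 CPM and the activin subunit gene INHBA from 3.01 ± 0.596 to 55.2 ± 2.15 CPM, while LTBP2 (-2.71 ± 0.08) and ID3 (-1.83 ± 0.06) fell. By limma-voom the TGF-beta list was no longer called (adjusted p = 0.319), and with each chromosome's median taken out its median was -0.03 against 0.24, with the camera direction still higher.

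Most tested markers of luminal cells fell. Of 15 tested, 9 fell and 2 rose (camera adjusted p = 7.48e-05, and adjusted p = 0.149 with an estimated correlation). KRT8 fell from 7564 ± 527 to 2450 ± 62.2 CPM, KRT18 from 3584 ± 195 to 1060 ± 20.6 CPM and the transcription factor gene ELF3 from 84.2 ± 4.47 to 17.3 ± 1.58 CPM, while CD24 rose (1.80 ± 0.06). KRT19 and MUC1 fell as well (-2.89 and -2.30). The epithelial adhesion genes EPCAM (0.01 ± 0.05) and CDH1 (-0.08 ± 0.04) did not pass the test. Of 13 basal markers, 8 fell and 3 rose (camera adjusted p = 0.0598, and adjusted p = 0.192 with an estimated correlation). TAGLN, an actin-binding protein of contractile cells, rose from 6.31 ± 0.183 to 578 CPM, and CDH3 and KRT14 rose (1.47 and 0.76), while KRT5 fell from 4679 ± 67.3 to 2018 ± 34.1 CPM and ACTA2 fell (-1.31 ± 0.07). The basal list passed the camera threshold without wild-type replicate 3 (adjusted p = 0.0158), without wild-type replicate 2 (adjusted p = 0.0354) and with scaling by library size only (adjusted p = 0.0480).

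Cell junction and polarity genes had 19 that fell and 5 that rose among 31 (camera adjusted p = 0.00561, and adjusted p = 0.112 with an estimated correlation). The desmosomal genes DSP (-1.67 ± 0.09) and PKP1 (-1.98 ± 0.10) and the tight junction gene TJP3 (-1.69 ± 0.08) fell, and CLDN8, at 4.40 ± 0.320 CPM in wild type, was at least 79.0-fold lower with 0 reads in knockout libraries. The gap junction gene GJB2 rose (1.47 ± 0.04), as did DSC3 (1.28 ± 0.09). With COL1A2 and CLDN8 set to their bounds, the mean of the matrix list went from 1.33 to 1.23 and that of the junction list from -0.71 to -0.61. The medians, 0.37 and -0.38, could not move, since both genes stay far beyond them at their bounds.

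Markers of other cell types did not move as 1 group. Of 13 fibroblast markers, 3 rose and 7 fell (camera adjusted p = 0.271, and adjusted p = 0.369 with an estimated correlation). The proteoglycan gene DCN fell from 1134 ± 106 to 229 ± 6.27 CPM and S100A4 from 2011 ± 181 to 462 ± 31.1 CPM. ZEB1 (2.72 ± 0.13) and SNAI1 (2.62 ± 0.23), transcription factors of the mesenchymal state, rose. VIM stood at 2.81 ± 0.432 CPM in knockout and 1.94 ± 0.593 CPM in wild type, which did not pass the test. The fibroblast list had a median of -0.36 and a mean of 0.54 (0.31 with COL1A2 at its bound), with the camera direction lower, and it passed the threshold without wild-type replicate 3 (adjusted p = 0.0455) and by DESeq2 (adjusted p = 0.0495). Endothelial markers had 3 that rose and 2 that fell (camera adjusted p = 0.122, and adjusted p = 0.354 with an estimated correlation), and passed the threshold with only genes of at least 1 CPM in 3 libraries (camera adjusted p = 0.0445, median 2.29 against 1.10). PECAM1 rose from 0.219 ± 0.0941 to 31.3 ± 0.886 CPM, and VWF fell by 3.85 ± 0.31 on the log2 scale.

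Pericyte and smooth muscle markers had 1 that rose (MCAM, 2.21) and 3 that fell (NOTCH3, MYH11 and CSPG4), with camera adjusted p = 0.404 and adjusted p = 0.617 with an estimated correlation. Adipocyte markers had 1 that rose (CIDEC, 1.98) and 1 that fell (PPARG, -3.26, and -4.59 to -2.86 with a library left out) among 4, with camera adjusted p = 0.953 and adjusted p = 0.956 with an estimated correlation. Leukocyte markers had 2 that rose (CSF1R and AIF1) and 1 that fell (CD74, -4.92, and -6.04 to -4.37 with a library left out) among 5, with camera adjusted p = 0.941 and adjusted p = 0.956 with an estimated correlation. For both the adipocyte and the leukocyte lists the median (-0.06 and -0.33) and mean (-0.35 and -0.38) were below 0 and camera gave the direction as higher. Of 7 squamous differentiation markers, 4 fell and 2 rose (camera adjusted p = 0.140, and adjusted p = 0.494 with an estimated correlation). IVL, named after a component of the cornified envelope and marked as a pseudogene in the count file, fell from 32.4 ± 2.44 to 2.00 ± 0.441 CPM, TGM1 fell by 3.84 ± 0.12 on the log2 scale, and the desmosomal cadherin gene DSG1 rose (5.20 ± 0.31).

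Interferon response genes had 26 that fell and 6 that rose among 38 (camera adjusted p = 0.00216, and adjusted p = 0.0912 with an estimated correlation). MX1, an antiviral GTPase, fell from 9.36 ± 0.518 to 0.392 ± 0.108 CPM and ISG15 by 2.76 ± 0.16 on the log2 scale. IFIT1 had 74 reads against 1 (ratio 72.7, counting interval 12.7 to 2912) and MX2 88 against 3 (ratio 28.8, interval 9.55 to 143). ISG20 and IFI6 rose (1.00 and 0.92), and IFIT3, at 1.06 ± 0.38, did not pass the test without wild-type replicate 3 (0.73, edgeR adjusted p = 0.0937), without knockout replicate 2 (0.80, adjusted p = 0.116) or by DESeq2 (1.08, adjusted p = 0.0751). Inflammatory and NF-kB genes went both ways, with 15 that rose and 10 that fell among 29 (camera adjusted p = 0.573, and adjusted p = 0.724 with an estimated correlation). The chemokine gene CCL2 rose from 0.619 ± 0.207 to 42.3 ± 2.16 CPM and PTGS2, the inducible prostaglandin synthase, from 39.3 ± 0.737 to 155 ± 2.75 CPM, while CXCL5 fell from 448 ± 13.4 to 125 ± 0.899 CPM and CCL5 by 3.55 ± 0.18 on the log2 scale.

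Of 30 mTOR and amino acid transport genes, 16 fell and 8 rose (camera adjusted p = 0.0328, and adjusted p = 0.149 with an estimated correlation). The members with the largest falls were DDIT4 and SESN3, both known as inhibitors of mTOR signalling, at -4.86 ± 0.10 and -4.68 ± 0.23. The next largest fall was that of the transporter gene SLC7A11 (-2.60 ± 0.51), which was hardly read in either genotype (45 reads in wild type against 7 in knockout libraries). AKT1, RHEB and the leucine transporter gene SLC7A5, known to promote growth signalling, rose (0.98, 0.80 and 0.82). MTOR itself (-0.68), RPS6KB1 (-0.61) and SLC38A2 (-1.12) fell, so the falls were not confined to inhibitors. Whether mTOR signalling changed was not tested. Of 27 hypoxia and glycolysis genes, 14 fell and 6 rose (camera adjusted p = 0.0328, and adjusted p = 0.159 with an estimated correlation). LDHA, which makes lactate, fell from 2626 ± 99.2 to 967 ± 7.93 CPM and NDRG1 from 1018 to 244 CPM, while VEGFA and HK2 rose (0.65 and 0.67). Neither list passed the threshold by limma-voom (adjusted p = 0.0985 and 0.0621).

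Of 17 Kruppel-like and SP factor genes, 10 fell, KLF6 among them, and 1 rose (camera adjusted p = 0.0253, and adjusted p = 0.149 with an estimated correlation). KLF9 (-2.51 ± 0.24), KLF2 (-1.31 ± 0.09), KLF10 (-1.27 ± 0.06) and KLF5 (-1.17 ± 0.05) fell, and KLF16 rose (1.07 ± 0.10). Immediate-early and heat-shock genes had 12 that fell and 9 that rose among 24 (camera adjusted p = 0.0208, and adjusted p = 0.322 with an estimated correlation). EGR1 fell from 200.4 ± 4.70 to 44.3 ± 1.10 CPM and FOS from 897 ± 63.7 to 231 ± 1.14 CPM, whereas the chaperone gene HSP90AA1 rose (0.61 ± 0.04). By limma-voom that list was not called (adjusted p = 0.319).

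Unfolded protein and stress response genes had 14 that rose and 12 that fell among 32 (camera adjusted p = 0.455, and adjusted p = 0.617 with an estimated correlation). MANF (1.43 ± 0.05) and HYOU1 (0.86 ± 0.04), which act in the endoplasmic reticulum, rose, while CHAC1 (-2.71 ± 0.15) and the serine synthesis gene PHGDH (-1.64 ± 0.05) fell. Nuclear genes of oxidative phosphorylation had 13 that rose and 10 that fell among 33 (camera adjusted p = 0.922, and adjusted p = 0.956 with an estimated correlation), with COX4I1 at 0.67 ± 0.06 and UQCRB at -0.70. Cytosolic ribosomal protein genes had 13 that rose and 14 that fell among 42 (camera adjusted p = 0.635, and adjusted p = 0.869 with an estimated correlation), with RPL13 at 0.52 ± 0.05 and RPL7 at -1.27 ± 0.04.

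**Figure D2:**
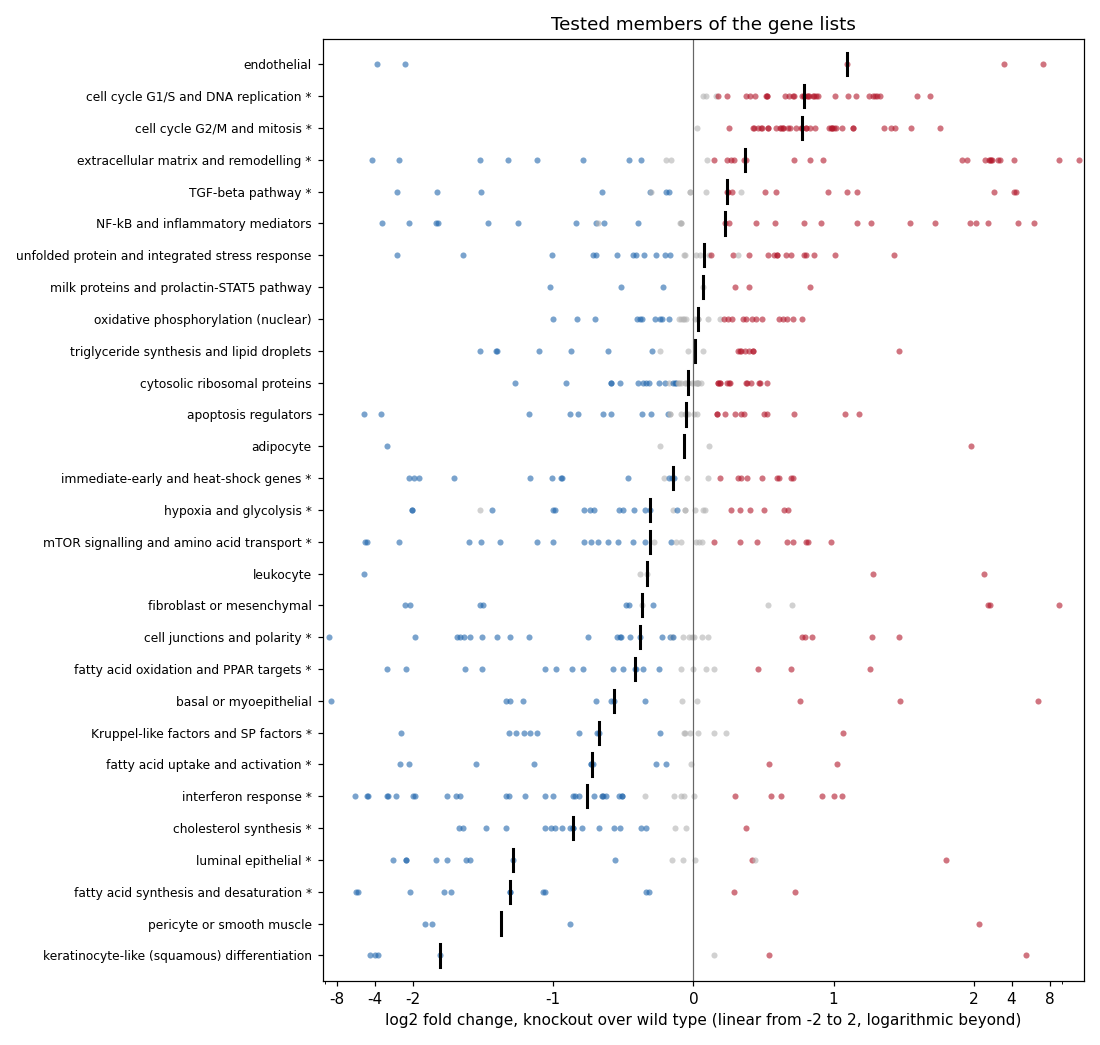
Log2 fold change of knockout over wild type (horizontal axis, linear between -2 and 2 and logarithmic beyond) for the tested members of the gene lists (rows, ordered by median). Points are genes, red for a called rise, blue for a called fall and grey for no call by edgeR, black bars are medians, and an asterisk marks the lists called by camera. No called member of the G1/S and G2/M lists lies below 0 (medians 0.79 and 0.77).

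In all, camera called 4 lists as higher and 11 as lower, and 0 of the 30 lists were called with an estimated correlation, where the lowest adjusted p was 0.0747. Adjusted over the list alone, the counts of members that rose or fell were the same for all lists but G1/S (33 rose) and fibroblast (4 rose). By fry, which asks whether a list's members move on balance in 1 direction, 27 lists were called.

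The median log2 fold change differed between chromosomes. Of the 301 tested genes on chromosome 14, 86.0% had a lower level in knockout libraries and the median was -0.82. Medians were also low on chromosomes 28 (-0.57), 12 (-0.43) and 3 (-0.39), and high on chromosomes 20 (0.48), 26 (0.45), 24 (0.37) and 18 (0.32). Of the 30 chromosomes, 24 lay outside the central 95% of 10000 shuffles of genes over chromosomes, where 1.5 would if single genes were placed at random. The shuffles set each chromosome against all genes pooled, shifted chromosomes included, and do not keep neighbours together. The 24 is therefore no count of chromosomes with a shift of their own. Chromosomes 13 and 25, for example, lay outside with medians of 0.078 each, against upper limits of 0.065 and 0.064. Genes named by rule include LYN, DGAT1, SQLE, NDRG1, CYC1, UQCRB, KLF10, RPL7 and RPL8 on chromosome 14, DDIT4 and EGR2 on 28, CCNB1, HMGCS1 and PLK2 on 20, and ACTA2, FAS, IFIT1, IFIT3, KIF11 and NDUFB8 on 26. With each chromosome's median taken out, an alternative added after the data were seen, RPL8 (-0.09, edgeR adjusted p = 0.104), FAS (0.07, adjusted p = 0.450), IFIT3 (0.61, adjusted p = 0.164), JAK2 (0.12, adjusted p = 0.212), UQCRB (0.12, adjusted p = 0.0513) and STAT5A (0.03, adjusted p = 0.718) no longer passed the test. Other genes of chromosome 14 kept their calls with folds that moved by over 1.5 times, among them DGAT1 (-0.58), SQLE (-0.82), NDRG1 (-1.24), KLF10 (-0.44), RPL7 (-0.45) and CYC1 (-0.18).

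**Figure D3:**
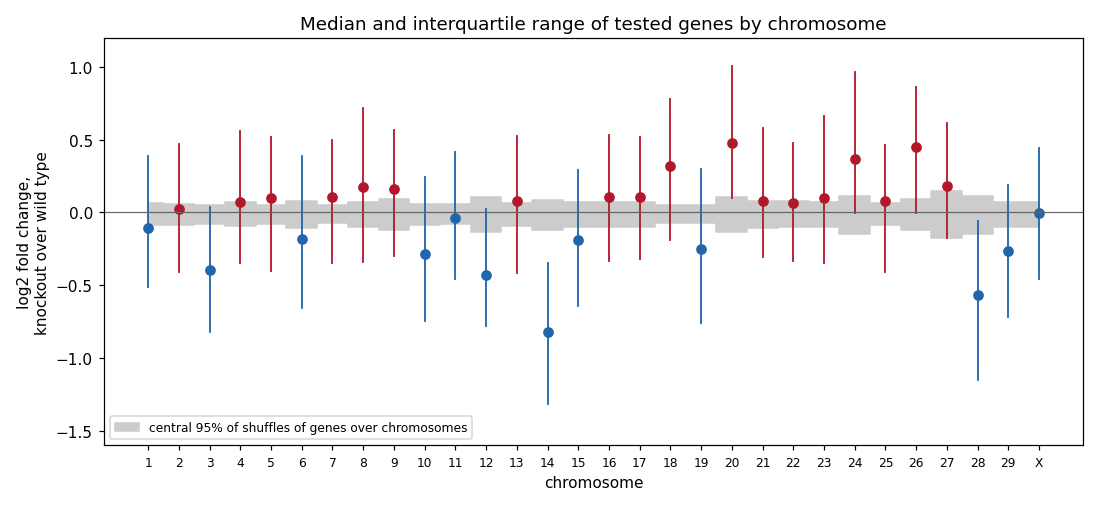
Log2 fold change of knockout over wild type (vertical axis) for the tested genes of each chromosome (horizontal axis). Points are medians (red above 0, blue below 0), lines are interquartile ranges, and the grey band holds the central 95% of medians when genes are shuffled over chromosomes. Chromosome 14 has the lowest median, at -0.82, and chromosome 20 the highest, at 0.48.

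The authors' deposited table lists 4936 genes as higher and 4596 as lower in knockout cells. Over the 9127 genes of the authors' deposited table that were tested here, its log2 fold changes and those of the edgeR fit had Pearson's r = 0.999 across genes, which are not independent replicates, and all had the same sign. Of the genes in the authors' deposited table, 9099 (95.5%) were called by edgeR, which called 892 more. DESeq2 run here on the same counts called 9547 genes, including all 9532 of the authors' deposited table.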

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

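The log2 fold change of KLF6 stayed between -1.29 and -1.16 under all alternatives, and between -1.24 and -1.16 when a library was left out. Leave-one-out counts of genes that rose ran from 4746 to 5115, and of genes that fell from 4746 to 5019. With at least a 2-fold change required, 1449 rose and 1538 fell, since a size limit removes small changes. Between 91.2% and 99.9% of the 9991 calls were kept in the same direction under the other scalings, tests and filters, the replicate block and leave-one-out, with 0 reversed. With the median of each chromosome taken out, added after the data were seen, 8411 (84.2%) were kept and 171 reversed, and r with the authors' deposited table was 0.988. By camera with an estimated correlation 0 lists were higher and 0 lower, and by fry 7 were higher and 20 lower, because fry tests each list without the other genes. Leave-one-out counts were 4 lists higher and 9 to 12 lower. Single results reversed as follows, and the cause was not tested. With the median of each chromosome taken out, STAT5A stood at 0.0339 and UQCRB at 0.12. The camera direction turned from higher to lower for the adipocyte list with the median of each chromosome taken out (median -0.26, already below 0 at -0.06) and without knockout replicate 3 (leave-one-out medians from -0.27 to 0.64), and from lower to higher for the milk protein list with no low-count filter (median 0.35, already above 0 at 0.07). Some list medians changed sign with the camera direction unchanged, among them leave-one-out medians of the leukocyte (-0.39 to 0.03), apoptosis (-0.09 to 0.01) and oxidative phosphorylation lists (-0.03 to 0.06). With a replicate block, 9894 genes were called. Correlations of the residuals between libraries of the same number were -0.10, 0.15 and -0.03. These gave no clear sign that the numbers pair the libraries, but 3 libraries per genotype are too few to exclude it.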

Other observations

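Some of the most abundant genes with at least a 4-fold change belong to no gene list, and were chosen after their values were seen. SPP1, which encodes the secreted matrix protein osteopontin, rose from 1044 ± 12.4 to 8314 ± 109 CPM in knockout libraries. IGFBP2, a binding protein of insulin-like growth factors, rose from 736 ± 88.3 to 3043 ± 111 CPM, and ALDH1A1, which makes retinoic acid, from 295 ± 6.24 to 1546 CPM. The ornithine aminotransferase gene OAT rose by 2.80 and the adhesion receptor gene PVR by 2.40 on the log2 scale.

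Among those that fell, CLU, an extracellular chaperone, went from 3913 ± 169 to 232 ± 5.84 CPM. PC, which makes oxaloacetate from pyruvate, fell from 1142 ± 42.2 to 146 ± 3.88 CPM, and the imprinted gene MEST from 614 ± 25.3 to 51.2 ± 2.69 CPM. The integrin subunit genes ITGB3 (-6.93 ± 0.10) and ITGB6 (-2.10 ± 0.04) fell, as did ESRP1 (-2.45 ± 0.05), a splicing regulator of epithelial cells that lies on chromosome 14.

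Chosen only after the results were seen were the 3 tests of chromosome shifts, the measures used below for whole chromosomes and gene length among all calls, and the use of plain library sizes in the test of abundant genes.

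Of the 13390 tested genes, 9991 were called. Of the 10 ways to split the 6 libraries 3 against 3, only 1, the real one, gave gene calls (9991, highest other 0) or 15 called lists (highest other 7). Every other split mixes the genotypes, so the genotype difference widens the spread within its groups, and few gene calls were favoured in advance. Part of that difference also stays between its groups, so its list calls are no measure of chance. Besides, 10 splits are too few for a share under 0.05, so the splits cannot decide whether chance gave the calls. Taking the 50 most abundant genes out of the library sizes shifted the median log2 fold change by 0.0157, too little to explain the calls. The bounds set beforehand decided neither for whole chromosomes (3.87% of the variance, largest median 0.82) nor for gene length (Spearman's rho -0.11). On the 19 chromosomes with a median within 0.2 of 0, 72.7% of genes were called. A shared shift of a gene's own chromosome was therefore not the whole cause of the calls. This share cannot exclude effects of shifted chromosomes on genes elsewhere. Gene length was not the whole cause either. After the length trend was removed, 2763 of the 2951 calls of at least 2-fold on placed chromosomes kept that size and direction. With those that newly reached it, the number was 2918. Passage, clone and genotype effects stay open and untested.

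The largest shift shared by the genes of a chromosome was not a chance arrangement of single genes. In 0 of 10000 shuffles of genes over chromosomes was a median as large as 0.82 (permutation p = 1.00e-04, the smallest they can give, with 0.31 the largest shuffled median). All 5 chromosomes with a median beyond 0.4 (14, 28, 12, 20 and 26) had the same sign in all 4 consecutive parts of equal gene number and in both weakly and strongly expressed genes. All 5 kept a median beyond 0.3 after the trend with gene length was removed. Since the 5 were chosen by these same medians, such agreement was favoured in advance. A difference in chromosome copy number between the knockout and wild-type cultures stays a hypothesis for these 5, which these checks cannot decide. Of the 24 chromosomes outside the shuffles, only 15 had all parts of 1 sign and 9 had parts of both signs. RNA levels alone cannot tell a copy number difference from regulation that spans a chromosome, and no biological explanation was tested.

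Of 21 protein-coding genes with at least 5 CPM in 1 genotype and 0 reads in the other, 8 were absent in knockout and 13 in wild-type libraries. A lost stretch of chromosome could take neighbours with it. A neighbouring gene changed at least 8-fold in the same direction for 14.3% of the 21 (interval 3.05% to 36.3%), against 4.92% of other genes. These were 3 genes, STEAP1, ZDHHC14 and USP26, all absent in wild type, and both neighbours of USP26 are unnamed loci. None of the 8 genes absent in knockout had such a neighbour, but 8 genes are too few to exclude a stretch lost in knockout cells. The share itself met the bound set beforehand against a lost stretch. Its interval, which that bound did not mention, reached beyond the bound, so this explanation stays open. No biological explanation was tested.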
